A study of Lathyrus oleraceus with 16 samples.

How the data were processed

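Shoot apical meristems of wild-type pea (Pisum sativum, also named Lathyrus oleraceus) of the cultivar Caméor were profiled by RNA-seq in 4 groups of 4 libraries, 16 in all. Per the labels, the plants grew in a greenhouse with 16 h of light and 8 h of dark, at 21.5 °C by day and 15 °C by night. Proliferative meristems came from plants that had made a flower bud but had not yet opened a flower. Arrested meristems were taken at the moment of proliferative arrest, the stage at which a fruiting plant stops making new flowers. Pruned meristems were taken on that same day from plants kept free of seeds by repeated pruning, which stayed active. Reactivated meristems were taken 24 h after all flowers and fruits had been cut from arrested plants. The labels call the 4 libraries of a group biological replicates and number them 1 to 4, with no statement that a number marks a shared batch or day. Apices were dissected by eye, with leaves and buds taken away as far as that allowed, so a library can hold some tissue from around the meristem.

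The values are raw counts of reads per gene, deposited by the authors as 1 table for all libraries. Per the labels, RNA was purified on columns and treated with DNase, and strand-specific libraries of polyadenylated RNA were sequenced on an Illumina NovaSeq instrument. Per the submitters' processing notes, cutadapt, HISAT2, HTSeq and DESeq2 were used, with no version or role stated. The deposited counts carry a name that says they were made with HTSeq without regard to strand. Reads from a gene and from an antisense or overlapping neighbour therefore could not be told apart, although the libraries kept the strand, and near-identical gene copies are uncertain as well. The genome build and the gene annotation were not given in the sources used here. Only whole numbers stood in the table, and 0 of its rows named something other than a gene.

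The table held 48559 gene IDs, of which 17007 had no count in any library. The IDs start with Psat. None could be tied to a name: 0 of 48559 matched the RefSeq gene table used here, which lists 65673 genes of the assembly CAAS_Psat_ZW6_1.0. No gene name, function or position is therefore given. The 55 gene lists fixed before the data were examined, covering the cell cycle, hormones, flowering, stress and other tissues, rested on names, descriptions or sequences and were not run. For the same reason, markers of other tissues that a dissected apex could hold were not analysed here. Genes are described instead by their behaviour over the 4 groups, and 4 IDs are given with their values.

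Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with too few counts were removed with edgeR's filterByExpr by group, which left 23979 genes holding at least 99.69% of the reads of each library. Libraries were scaled with TMM factors, which assume that most genes change little or in balance; that assumption is weak where most genes are called, so splits of direction are also given with library totals where they differ by over 10 percentage points or the majority turned. All 16 libraries entered a single quasi-likelihood fit (glmQLFit, glmQLFTest) with the group as the only term, so that the groups shared an estimate of the spread. All 6 pairs of groups were tested, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F. The CPM of a single gene is its count scaled by the library total, and log2 CPM for plots and profiles used TMM factors and a prior count of 2. Single values per library were compared with two-sided exact permutation tests, whose smallest possible p is 0.0286 with 4 libraries against 4.

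A gene set a group apart if it was called in the same direction against each of the other 3 groups. The return after 24 h was measured with the Arrested libraries split 2 and 2 in all 6 ways. Genes were called with 1 pair against Pruned, and the other pair was set against Reactivated, so that no Arrested library entered both sides. The return ratio of a gene is the change from Arrested to Reactivated, with its sign turned, divided by the change from Pruned to Arrested. Each gene called between Arrested and Pruned was also given a profile from its calls in Reactivated. It was called back if it differed from Arrested in the direction of Pruned and had no call against Pruned, and part way back if it still differed from Pruned on the Arrested side. It was called beyond Pruned if it differed from Pruned on the opposite side, and not back if it had no call against Arrested and still differed from Pruned. The remaining genes moved further from Pruned or were undecided. These profiles, and the use of all reads in set-apart genes, were chosen after the counts of called genes had been seen. A gene counted as silent in a group at 3 or fewer counts over its 4 libraries, and as on at 1 CPM or more in each library.

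The rule for single genes was fixed before the data were examined. Among genes with an adjusted p under 0.05 between Arrested and Pruned, a mean of at least 5 CPM over both groups and no overlap between the log2 CPM values of the groups, it takes the 2 largest rises and the 2 largest falls where IDs have no names. Chance gives no overlap in 2.86% of genes with 4 libraries against 4. Folds of single genes were taken from counts pooled over the libraries of a group. A fold against a group with 0 counts was computed against 3 counts over the group and is a lower bound, and a fold against a group with 1 to 3 counts has an exact Poisson interval at the 95% level. These bounds and intervals cover counting error only, since PCR copies are not independent molecules.

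Totals ran from 16264221 to 24435174 counts per library, so 3 counts over the 4 libraries of a group stand for 0.0378 to 0.0387 CPM. The test was tried on simulated data for Arrested against Pruned, over 23979 genes with real levels, library sizes and spreads and 200 changed genes. It recovered 15.2% of changes of 0.5 on the log2 scale, 40.3% of changes of 1 and 91.0% of changes of 2, with 2 unchanged genes called. In 20 simulated data sets with no change, at most 2 genes were called in a comparison and 0 set Arrested apart. Genes were simulated independently of each other, so variation that many genes share within real groups is left out. These counts are therefore no rate of false calls for the real data. A simulated return of 0.75 was estimated as 0.729. Of fully returned genes 89% were called back, but only 28% of genes that had returned halfway were called part way back. No libraries of a group agreed within sampling noise, the lowest chi-square per degree of freedom being 11.1.

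Alternatives listed before the data were examined were RLE factors, library totals, no filter, a stricter filter of 1 CPM in at least 4 libraries, DESeq2 1.42.0, limma 3.58.1 with voom, fits of only the 2 groups compared, the replicate number as a block, each library left out in turn, and Proliferative as the active reference of the return. Added after the data were seen were fits without the 3 libraries that carry a restricted block of genes, fits with the score of a within-group axis as a covariate, and library totals for the set-apart genes and the return.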

Results

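Gene expression was measured in the shoot apical meristem of pea to ask how seeds influence proliferative arrest, the end of flower production in a fruiting plant. The 16 libraries fall into 4 groups of 4. Meristems were active before the opening of any flower (Proliferative), arrested on fruiting plants (Arrested), active on plants of the same day that had been pruned and had never borne seeds (Pruned), or active again 24 h after all flowers and fruits had been cut from arrested plants (Reactivated). Total counts per library ran from 17588462 to 24051585 in Proliferative, from 17459226 to 21462529 in Pruned, from 16264221 to 24435174 in Arrested and from 17690746 to 22463721 in Reactivated, so the groups overlapped in depth. The number of genes with 1 or more counts was 26831 ± 648 in Proliferative, 26894 ± 339 in Pruned, 25925 ± 435 in Arrested and 26009 ± 211 in Reactivated (SD, n = 4). Relative to Pruned it decreased by 885 in Reactivated (exact permutation test, p = 0.0286). In Arrested it decreased by 969, which did not pass the same exact permutation test (p = 0.0571).

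Arrested meristems stood apart from the 3 active groups in their whole expression profile. The leading principal component of log2 CPM held 59.9% of the variance and placed the Arrested libraries between 182.6 and 208.7 and the other 12 between -90.8 and -36.8. The second component held 15.8% and separated Reactivated, between -106.7 and -84.5, from Proliferative and Pruned, between 30.9 and 64.5. Arrested libraries correlated with those of the active groups at a mean r across genes of 0.728 for Pruned, 0.747 for Reactivated and 0.766 for Proliferative, and with each other at 0.972. Proliferative and Pruned libraries correlated with each other at 0.942, close to the 0.950 and 0.951 within these groups, and with Reactivated libraries at 0.910 each. These correlations are across genes, which are not independent replicates.

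**Figure D1:**
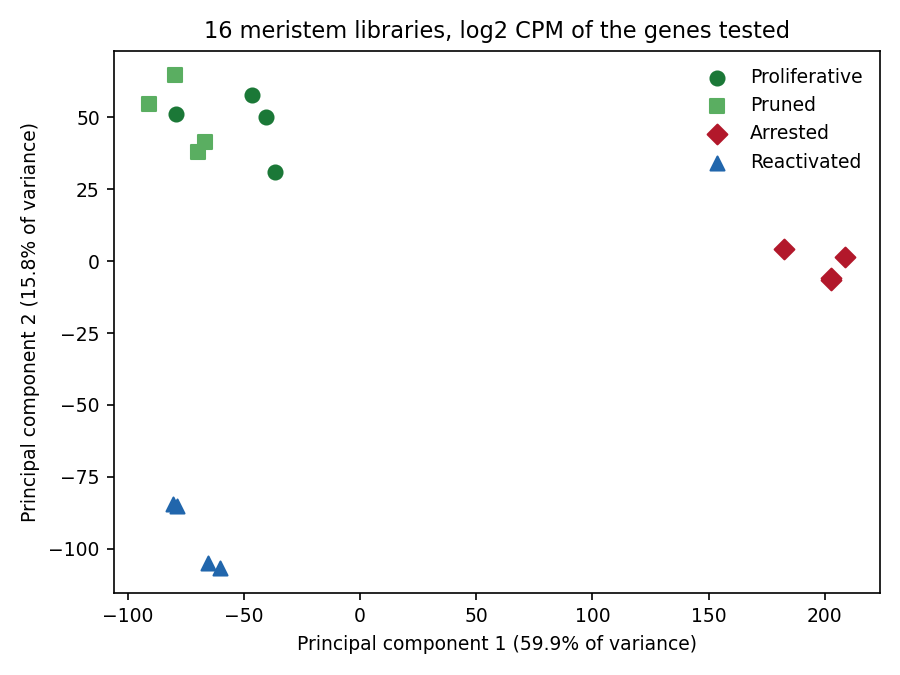
Principal components 1 and 2 of log2 CPM (no unit) for the 16 libraries, 1 point per library, with the share of variance on each axis. The 4 Arrested libraries lie at 182.6 to 208.7 on component 1, and the 4 Reactivated libraries lie below the other active libraries on component 2.

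Arrested and Pruned meristems were collected on the same day and differ in whether the plant carried seeds, in the repeated pruning and in whether the meristem was active, which this contrast cannot separate. Most of the transcriptome differed between them: 7568 genes were higher and 8777 lower in Arrested, 68.2% of the 23979 tested. Which direction held the majority was not stable, since 8945 were higher and 7415 lower with library totals in place of TMM factors, and 7933 and 7760 when only these 8 libraries were fitted. The changes were large, with a median size of 1.35 on the log2 scale, and the median did not move when genes with 0 counts in a group were set to their bounds. Counted that way, 1123 genes were over 8-fold higher and 1677 over 8-fold lower in Arrested. A small set of genes switched between silent and on: 104 genes at 1 CPM or more in every Arrested library had 3 or fewer counts over the 4 Pruned libraries, and 49 showed the opposite. Calls rest on edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the median standard error of a log2 fold change was 0.22.

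The rule for single genes was met by 5403 rises and 5871 falls, and its most extreme members showed nearly complete on and off states. Psat1g095640 had 0 counts in the 4 Pruned libraries and 203 CPM ± 73.8 in Arrested, at least 5301-fold higher. Psat5g242640 had 1 count over the Pruned libraries and 146 CPM ± 88.7 in Arrested, a ratio of 11240 with a 95% Poisson interval of 2017 to 443980. Psat4g021920 had 124 CPM ± 83.1 in Pruned and 0 counts in Arrested, at least 3414.5-fold lower, but Pruned 3 stood at 2.81 CPM and the other 3 Pruned libraries at 143 to 189. Psat5g306240 had 79.1 CPM ± 36.8 in Pruned and 0 counts in Arrested, at least 2128.5-fold lower (SD, n = 4 throughout). These folds rest on counts pooled over the 4 libraries of a group, 202, 143, 129 and 80.7 CPM in the order given, and not on the means. In edgeR's quasi-likelihood test the adjusted p was 1.91e-09 for Psat1g095640, 1.31e-06 for Psat5g242640, 0.000135 for Psat4g021920 and 3.56e-08 for Psat5g306240. Their fitted log2 fold changes of 14.74, 12.72, -14.24 and -13.59, with standard errors of 0.77, 1.48, 2.39 and 0.96, depend on the fit's prior count and are no measure of the true fold. The files do not pair these IDs with names, and an antisense or overlapping neighbour could not be separated from any of them.

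Against Proliferative, the active meristem of a younger plant, Arrested showed 7347 genes higher and 8412 lower, 65.7% of those tested by the same edgeR test. The majority was again reversed, with 8835 higher and 7011 lower with library totals and 7583 and 7358 when only these 8 libraries were fitted. The median size of a called change was 1.28 on the log2 scale. Psat1g095640 was at 0.0426 CPM ± 0.0853 in Proliferative and Psat5g242640 at 1.28 ± 2.52, against 203 and 146 CPM in Arrested, while the genes silent in Arrested, Psat4g021920 and Psat5g306240, stood at 49.4 CPM ± 36.9 and 41.7 ± 4.67 (SD, n = 4). Psat4g021920 was at 0.280 CPM in Proliferative 1, against 41.8 to 78.7 in the other 3 libraries. In Proliferative, 89 of the 90 counts of Psat5g242640 came from replicate 3. Of the 104 genes on in Arrested and silent in Pruned, 28 were silent in Proliferative and 0 were on in all of its libraries, and of the 49 genes silent in Arrested and on in Pruned, 26 were on in Proliferative.

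The lists of genes that separated Arrested from both never-arrested groups overlapped in 14461 genes of the same direction, 6598 higher and 7863 lower. Independent lists of these sizes would share 2319 and 3079. Simulated unchanged groups shared 0, but had 0 calls in either comparison, so they give no scale for this overlap. With different Arrested libraries on each side, 2 against 2, the overlap was 12072 genes on average over 6 splits, where independent lists would share 1824 higher and 2373 lower. Against all 3 active groups, 5876 genes were higher and 6786 lower in Arrested, 12662 in all. The same count was 5499 for Reactivated, 307 for Pruned and 92 for Proliferative. The last 2 counts cannot exceed the 886 calls between Pruned and Proliferative, so they give no scale for the Arrested count. The direction of the Arrested set depended on scaling: with library totals in place of TMM factors, 7631 genes were higher and 4964 lower.

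The genes that set Arrested apart made up much of the sequenced RNA. The 5876 higher genes took 42.7% of all counts ± 1.38 in Arrested, against 12.1% ± 0.69 in Pruned, 13.7% ± 0.76 in Proliferative and 7.92% ± 0.30 in Reactivated. The 6786 lower genes took 23.9% ± 0.88 in Arrested, 58.0% ± 2.30 in Pruned, 56.6% ± 0.73 in Proliferative and 68.2% ± 1.62 in Reactivated (SD, n = 4 each; exact permutation p = 0.0286 for Arrested against Pruned in both sets). These genes were chosen on the same libraries, so their shares are not independent evidence of direction. The 10 most abundant genes of each library held 4.85% of counts ± 0.46 in Arrested and 3.85% ± 0.22 in Reactivated, against 2.70% ± 0.19 in Pruned and 2.69% ± 0.30 in Proliferative (SD, n = 4; exact permutation p = 0.0286 for Arrested and for Reactivated against Pruned).

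**Figure D2:**
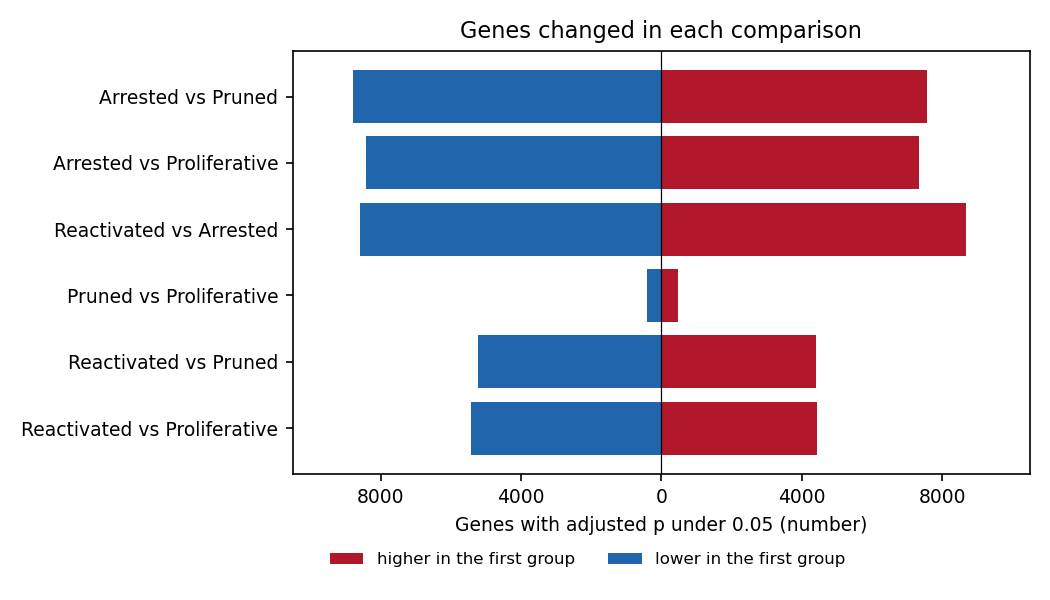
Number of genes called higher (right) and lower (left) in the group named first, for each of the 6 comparisons, at an adjusted p under 0.05 with TMM scaling. Comparisons with Arrested reach 15759 to 17275 genes, and Pruned against Proliferative 886. With library totals, and with only the 2 groups fitted, most calls were higher in both comparisons of Arrested with a never-arrested group, and the split of each Reactivated comparison moved too, 33.4%, 18.8% and 18.5% of calls being higher with library totals against Arrested, Pruned and Proliferative.

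Reactivated meristems were taken 24 h after the flowers and fruits had been removed from arrested plants, which asks how far expression leaves the arrested state within that time. Reactivated differed from Arrested in more genes than any other pair of groups, with 8695 higher and 8580 lower, 72.0% of those tested with edgeR. This near-even split turned to 8141 and 9127 when only these 8 libraries were fitted, to 9266 and 9278 with a within-group axis as a covariate, and to 8305 and 8453, 8305 and 8615, 8351 and 8570, and 8303 and 8448 without Reactivated 1, 2, 3 and 4. Of the genes on in Arrested and silent in Pruned, 32 of 104 were also silent in Reactivated and 9 were on in all of its libraries. Of the genes silent in Arrested and on in Pruned, 12 of 49 were on and 2 were silent. Psat1g095640 was at 61.1 CPM ± 20.8 in Reactivated, lower than in Arrested by a log2 fold change of -1.15 (SE 0.32, edgeR adjusted p = 0.00588). Psat5g242640 was at 7.28 CPM ± 1.87, with a log2 fold change of -3.76 (SE 0.78, edgeR adjusted p = 0.000409). Psat5g306240, with 0 counts in Arrested, reached 14.03 CPM ± 8.61 (edgeR adjusted p = 2.39e-07). Psat4g021920 had 7 counts over the 4 Reactivated libraries, 0.0937 CPM ± 0.110, and its rise from 0 did not pass the test (edgeR adjusted p = 0.555; SD, n = 4 throughout). With library totals in place of TMM factors, 33.4% of the calls between Reactivated and Arrested were higher in place of 50.3%, since the median of all genes then lay at -0.58 on the log2 scale.

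Most genes that differed between Arrested and Pruned had a change of opposite sign between Arrested and Reactivated. Genes are said to have risen or fallen at arrest where they were higher or lower in Arrested than in Pruned. Those groups are different plants that also differ in pruning, so these are no changes followed over time. Of the 16345 genes called between Arrested and Pruned, 13638 were also called in the opposite direction between Arrested and Reactivated, where independent lists would share 2708 that rose and 3183 that fell at arrest. Simulated unchanged groups shared 0, but had 0 calls between Arrested and Pruned, so they give no scale here either. With separate Arrested libraries on each side, 14536 genes per split were called between Arrested and Pruned, and 11867 of them on average were called in the opposite direction between Arrested and Reactivated. Counting signs alone, whether or not the later change passed the test, 94.4% had the opposite sign, with a range of 93.7% to 94.8% over the 6 splits. This share of signs was 95.3% for genes that had risen and 93.6% for genes that had fallen. The median return ratio was 1.02, from 0.966 to 1.08 over the splits, where 1 is a return to the level of Pruned. It was 1.05 for risen genes and 0.987 for fallen genes with TMM factors, but 1.31 and 0.748 with library totals. With Proliferative as the active reference, the median return ratio over all called genes was 1.10. The splits share libraries, so their range is not a replicate error.

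The 7568 genes higher and 8777 lower in Arrested than in Pruned fell into distinct profiles at 24 h. Among the higher genes, 4177 (55.2%) were back, 1768 (23.4%) lay beyond Pruned, 529 (6.99%) were part way back and 530 (7.003%) were not back. Among the lower genes, 3994 (45.5%) were back, 2185 (24.9%) lay beyond Pruned, 985 (11.2%) were part way back and 887 (10.1%) were not back. A further 136 higher and 183 lower genes moved further from Pruned, and 428 and 543 were undecided. Genes part way back, a profile that needs a call on both sides and so favours genes with large changes, had a median of 2.29 in Arrested and 0.90 in Reactivated for higher genes, and of -3.06 and -1.04 for lower genes, relative to Pruned on the log2 scale. Genes not back had medians of 0.82 in Arrested and 0.82 in Reactivated when higher, and of -1.48 and -1.49 when lower. Genes beyond Pruned crossed from 1.20 to -0.83, or from -1.05 to 0.84. The genes were sorted into profiles by calls on these same libraries, so the side on which each median lies is set by the sorting. A gene counted as back only lacks a call against Pruned, which does not show a full return. In the simulated data only 28% of genes that had returned halfway were called part way back. The counts of back genes may therefore hold genes that returned in part. The profile counts also depended on the fit. With library totals 3945 higher and 2748 lower genes were back, and 4066 and 1082 lay beyond Pruned. On that scale 279 and 1346 were not back, 63 and 341 moved further from Pruned, and 239 and 541 were undecided. Genes that moved further became 228 and 275 with the axis covariate, and undecided genes 654 and 962 with no filter on low counts.

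**Figure D3:**
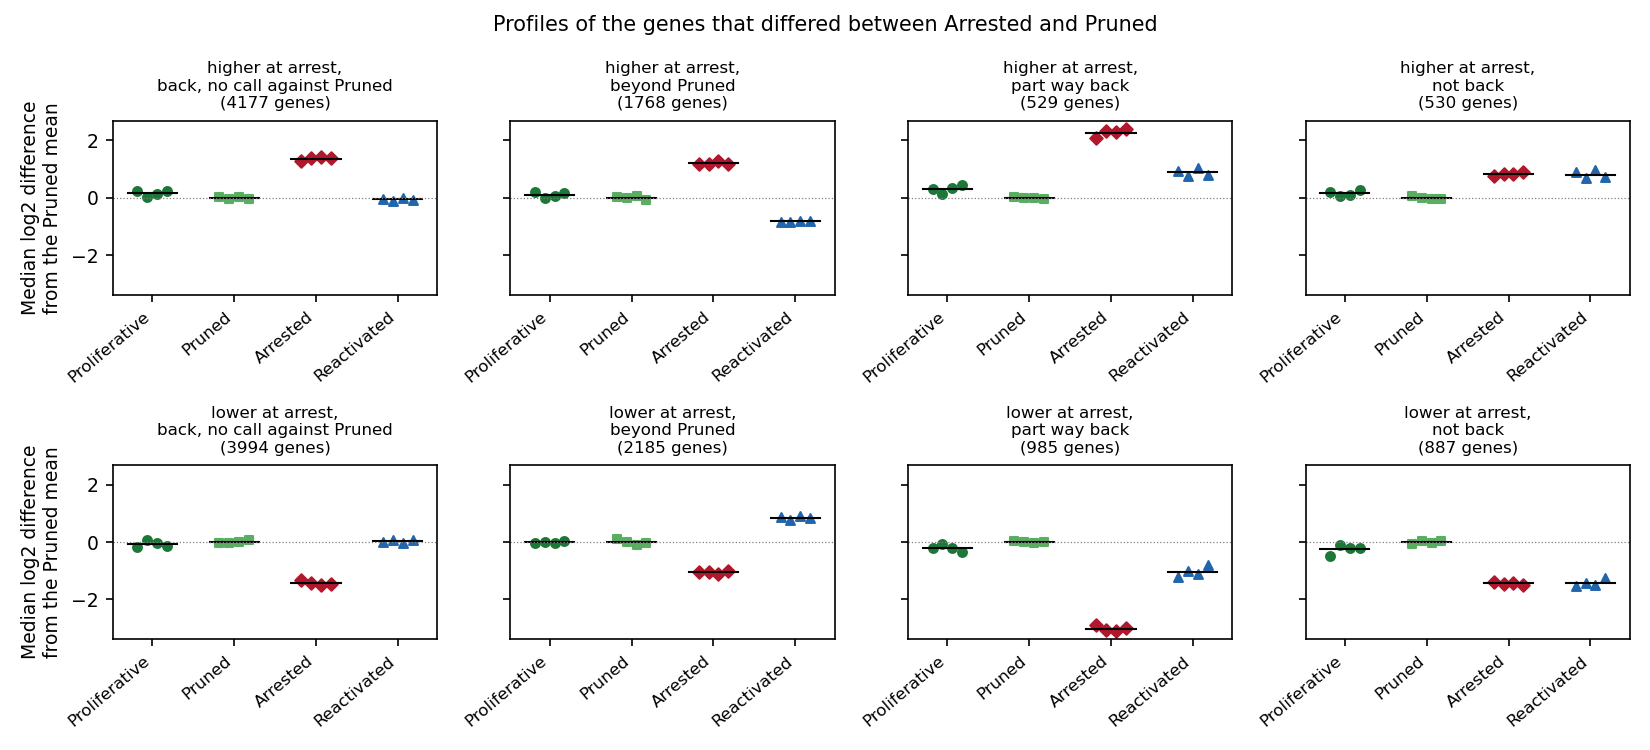
Median log2 difference from the Pruned mean over the genes of each profile, 1 point per library and a line at the group mean, for genes higher (top) and lower (bottom) in Arrested than in Pruned. Genes that were back lie near 0 in Reactivated, and genes beyond Pruned lie on the opposite side, at -0.83 and 0.84 in the median. These positions follow from sorting the genes by calls on the same libraries. The sizes of these profiles changed with library totals as the scale.

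Reactivated meristems also differed from the active meristems that had never arrested. In every Reactivated comparison, a response to the cutting 24 h before and any difference in the time of collection cannot be separated from reactivation. Against Pruned, 4396 genes were higher and 5225 lower, 40.1% of those tested, with a median size of 0.94 on the log2 scale. Against Proliferative, 4431 were higher and 5422 lower, 41.1% of those tested, with a median size of 0.93. In all, 2874 genes were higher and 2625 lower in Reactivated than in each of the other 3 groups. Of these 5499 genes, 3577 differed between Arrested and Pruned in the other direction, and 1630, with 744 higher and 886 lower, had no call between Arrested and Pruned. The 2874 higher genes took 55.6% of counts ± 2.46 in Reactivated, against 32.002% ± 1.73 in Pruned, 32.6% ± 1.16 in Proliferative and 20.03% ± 0.53 in Arrested. The 2625 lower genes took 3.38% ± 0.21 in Reactivated, against 8.74% ± 0.41 in Pruned, 9.63% ± 0.76 in Proliferative and 21.4% ± 0.69 in Arrested (SD, n = 4; exact permutation p = 0.0286 for Reactivated against Pruned in both sets, which were chosen on these libraries). The TMM factor was 0.795 ± 0.036 in Reactivated and 1.03 ± 0.053 in Pruned (SD, n = 4). With library totals, 18.8% of the calls against Pruned and 18.5% of those against Proliferative were higher, in place of 45.7% and 44.97%, with medians of all genes at -0.45 and -0.46 on the log2 scale.

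Pruned and Proliferative meristems were both active and free of seeds, and differed in the age of the plant and in pruning. This was the smallest difference of the 6: 466 genes were higher and 420 lower in Pruned, 3.69% of those tested with edgeR. Chance was not excluded for it, since 2 of 35 splits of the same libraries, the real one included, gave as many genes as the real split. The median size of a called change was 1.32 on the log2 scale, and 65 genes were over 8-fold higher and 75 over 8-fold lower with genes at 0 counts set to their bounds. Of the 886 genes, 446 changed in the opposite direction between Proliferative and Arrested, 241 in the same direction and 199 had no call there. Independent lists would share 292 and 290, and both comparisons use the same Proliferative libraries. Psat1g095640, Psat5g242640, Psat4g021920 and Psat5g306240 had no call between these groups (edgeR adjusted p of 0.687, 0.170, 0.637 and 0.298).

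The number of genes called between Pruned and Proliferative was unstable. It fell to 223 when only these 8 libraries were fitted. It was 95 without Proliferative 3, Proliferative 4 and Pruned 2, the libraries that carry a block of genes seen almost nowhere else. That fit also left fewer libraries in both groups, and the filter had removed the block genes from all tests. The fall can therefore not be put down to the block. The number was 607 without Proliferative 3, 582 without Proliferative 4, 574 without Pruned 2 and 586 without Pruned 3. It rose to 1552 with DESeq2. With the score of a within-group axis as a covariate it was 2068, but that score is drawn from the residuals of the same libraries, so fitting it narrows the residual spread, and the counts of all 6 comparisons rose with it. The split of directions, 466 higher and 420 lower, moved as well: it was 169 and 54 with only these 8 libraries, 472 and 474 with library totals, 427 and 599 without Proliferative 2, 554 and 311 without Pruned 4, and 958 and 1110 with the axis covariate. That axis, the leading component of the variation inside groups, ran from -60.6 to 65.0 in Proliferative and from -43.4 to 63.6 in Pruned, and held 31.4% of the variance within groups.

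**Figure D4:**
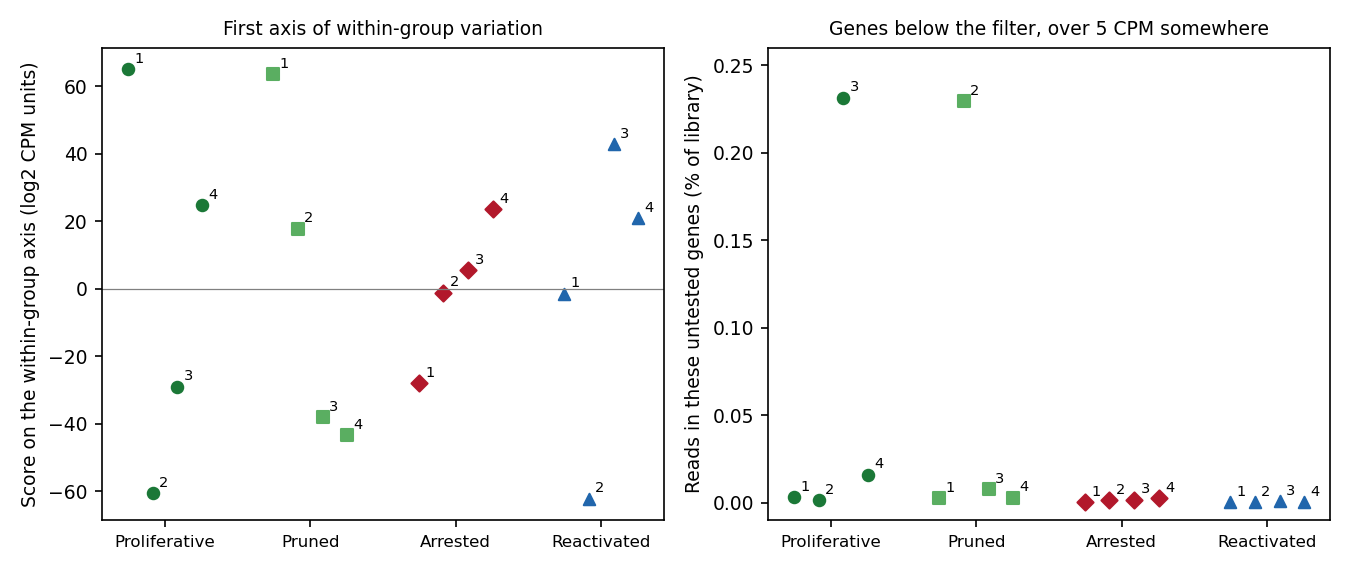
Left, score of each library on the leading axis of variation inside groups (log2 CPM units, points numbered by replicate); right, percent of counts in genes below the filter that reached 5 CPM in some library. Proliferative and Pruned libraries spread from -60.6 to 65.0 on the axis, and Proliferative 3 and Pruned 2 stand at 0.232% and 0.229% on the right.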

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

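All tests of explanations in this part were chosen after the results they bear on had been seen. Single libraries were set against the other 3 of their group by Dixon's test in 56 groups of values. In 8 of them a library stood apart, where chance gives about 1 in 20, or 2.8, for independent normal values. That rate is no yardstick here. A gene with counts in a single library of a group is always flagged, and the untested genes were chosen for being high in some library.

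A block of genes outside all comparisons was found in Proliferative 3 and Pruned 2. Among genes removed by the filter, 140 reached 5 CPM in some library, and 94 did so in both of these libraries. None of the 94 passed 1 CPM in any of 13 other libraries, Proliferative 4 not being among the 13. The filter removes only genes that are low in most libraries, so this absence elsewhere is largely set by the choice of genes. Genes that passed the filter were not searched for the same pattern. The 140 genes took 0.232% of counts in Proliferative 3 and 0.229% in Pruned 2, each far above the rest of its group, 0.0161% in Proliferative 4 and at most 0.00763% elsewhere. The 94 genes had a median ratio of Proliferative 3 to Pruned 2 of 1.10, with quartiles of 0.879 and 1.41.

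Exchange of reads or RNA between Proliferative 3 and Pruned 2 could account for the block only if other genes had passed with it at the same ratio. The 63 genes over 2-fold higher in the other Pruned than in the other Proliferative libraries stood in Proliferative 3 at a median of 0.124 of their Pruned 2 level, at most 0.530 (0.0417 and 0.0208 for the 19 and 5 genes at cutoffs of 4-fold and 8-fold, which were tried earlier). In the reverse direction, 9 genes stood at a median of 0.159, at most 0.563, so exchange in either direction is argued against. A tissue of fixed makeup in all 3 libraries stays open: over 81 block genes the log2 ratio of Proliferative 4 to Pruned 2 had an interquartile range of 2.42, but this decides nothing against the 0.511 that counting alone gives, since Proliferative 3 to Pruned 2 had 0.683 over the 94 genes, above 0.511 as well. Also open are a piece of another organ, RNA of another organism or a state shared by Proliferative 3 and Pruned 2, since the IDs have no names and no markers were analysed here; the groups do not divide these libraries from the rest, so no biological explanation was tested.

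The other values were flagged because 1 library lay far from its group. Psat5g242640 was at 5.06 CPM in Proliferative 3, from 89 counts, against 1 or 0 counts in the other Proliferative libraries. It was at 0.0466 CPM in Pruned 4, a single count. Psat1g095640 was at 0.171 CPM in Proliferative 3, from 3 counts, against 0 in the other 3. Reads in genes that set Arrested apart upward were 12.6% of the counts of Proliferative 2, the lowest of its group. Reads in genes that set Reactivated apart upward were 34.4% of the counts of Proliferative 4, the highest of its group. Reads in the 140 untested genes were 0.00108% of the counts of Reactivated 3, the highest of its group.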

How the results depend on the processing

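Library totals for the set-apart genes and the return, fits without Proliferative 3, Proliferative 4 and Pruned 2, and fits with the within-group axis as a covariate were added after the data had been seen; the other alternatives were listed before. Apart from Pruned against Proliferative, each comparison stayed within 1.5 times its count under all 18 alternatives run, from 15555 to 17891 genes for Arrested against Pruned, 14015 to 17383 for Arrested against Proliferative, 16584 to 18544 for Reactivated against Arrested, 8033 to 12114 for Reactivated against Pruned and 7278 to 12336 for Reactivated against Proliferative. The genes that set Arrested apart ran from 11660 to 14009 over 23 alternatives. These are sizes of lists and do not show that the same genes were called. With library totals, 7504 of 9621 calls between Reactivated and Pruned were shared in the same direction. The same held for 7704 of 9853 calls between Reactivated and Proliferative and 14529 of 17275 between Reactivated and Arrested. Pruned against Proliferative, 886 genes, became 1552 with DESeq2, 223 with only the 2 groups, 95 without the 3 libraries of the restricted block, 574 to 1026 with each library left out, and the cause was not tested; it became 2068 with the axis covariate, which by construction narrows the residual spread and raised the count of all 6 comparisons. The share of genes with a change of opposite sign after 24 h, 94.4%, was 95.3% with Proliferative as the active group and 93.5% with library totals, and the cause was not tested. The 4 named genes kept their direction and passed the test under the 11 alternatives run for them, with adjusted p at most 0.000729. These were RLE factors, DESeq2, the replicate block and each Arrested or Pruned library left out. The other alternatives were not run for these genes. Library totals turned the majority of calls from lower to higher for Arrested against Pruned, Arrested against Proliferative and the genes that set Arrested apart, and from higher to lower for Reactivated against Arrested. Fits of only the 2 groups turned the majority of the same 3 comparisons, and Reactivated against Arrested, near even, turned as well with the axis covariate and without any 1 Reactivated library. Library totals moved the median of all genes from -0.10 to 0.10 for Arrested against Pruned. Reads in genes that set Arrested apart upward, 42.7% in Arrested, were 39.2% without the 3 block libraries and 51.1% with library totals. The replicate numbers did not pair the libraries: same-numbered libraries of different groups correlated in their deviations at -0.319 to 0.588, only 3 of 24 pairs above 0.1, and the best match was the own number in 7 of 48 cases. With the replicate block the counts were 15922, 15295, 16940, 603, 8944 and 9169 in the order of Arrested against Pruned and Proliferative, Reactivated against Arrested, Pruned against Proliferative, and Reactivated against Pruned and Proliferative, and 12329 for the genes that set Arrested apart. The alternatives for the fixed gene lists were not run, and neither the block nor left-out libraries were applied to the return, whose splits leave 2 Arrested libraries a side. At this depth and n = 4, a 2-fold change was found in 40.3% of simulated genes for Arrested against Pruned. Only 200 genes were changed there, which makes the adjusted cutoff stricter than with the 16345 genes called in the real comparison. The share is therefore not the power of that comparison. Genes without a call are still not shown to be unchanged.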

Other observations

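The tests of the within-group axis, of neighbouring IDs, of Pruned lying away from Arrested, and of other splits for Arrested against Pruned and Pruned against Proliferative were chosen after the results had been seen. Complete switches of single genes differed between comparisons. Between Arrested and Reactivated, 73 genes on in all Arrested libraries were silent in Reactivated, and 24 went the other way. Between Pruned and Reactivated, 14 genes were silent in Reactivated and 11 in Pruned, and between Proliferative and Pruned 0 genes were silent in Pruned and 1 in Proliferative. The spread between libraries, as the median SD of log2 CPM over genes, was 0.231 in Arrested, 0.270 in Reactivated, 0.299 in Pruned and 0.305 in Proliferative; the difference was not tested.

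Variation inside the groups was described by its leading axis, the leading component of log2 CPM after removal of the group means. It held 31.4% of the variance within groups. In 4566 genes the deviation from the group mean correlated with the score at an absolute r over 0.8, 1966 rising and 2600 falling. The score was drawn from these same deviations, so the count is not separate evidence. Drawn in each group alone, the axis correlated between groups at 0.211 to 0.565 across genes, which are not independent. The sign in each group was set to match the joint axis, and no value for unrelated axes was computed. An axis common to the groups is therefore not established. With both measures centred on the group means, the score followed the number of genes detected over the 16 libraries at r = -0.867 (permutation p = 3e-05, adjusted 7.5e-05; rho = -0.856, permutation p = 8e-05; r = -0.882 without the 2 farthest libraries). It followed the TMM factor at r = -0.878 (permutation p = 5e-05, adjusted 7.5e-05; rho = -0.850, permutation p = 3e-05; r = -0.866), but not the total count at r = -0.153 (permutation p = 0.600, adjusted 0.600; rho = -0.0471, permutation p = 0.875; r = 0.0884), 3 relations in all.

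Library depth is argued against as the whole cause of the axis, since the r of -0.153 with the total count had a 95% interval of -0.649 to 0.435, where depth as the cause needs a size over 0.8. A wrong scaling factor as the cause was not decided. It would move all genes of a library alike. Equal loadings of all genes carried 8.695% of the axis with library totals as the scale, from 5.95% to 10.9% with each library left out. But that scale holds the sum of each library fixed, so a low share was largely set in advance. The axis was also drawn anew on that scale. The share shows only that what remained after scaling was mostly no common shift. The TMM factor is computed from the composition of the RNA, so its relation to the score does not decide the question of scaling either. Libraries part way to arrest are argued against as the whole cause, since the loadings correlated with the changes between Arrested and Pruned at 0.215 across genes, from 0.119 to 0.265 with each library left out. A varying share of leaf or bud tissue left on the apex remains open: it may add detected genes at an end of the axis, as the r of -0.867 shows, but any broad change in the RNA could do the same, and no tissue markers were analysed here. Group means were removed before the axis was drawn, so it cannot be set against the groups, and no biological explanation was tested.

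A hypothesis from the opposite directions of the calls is that Pruned meristems may lie on the far side of Proliferative from Arrested. It was examined with the Proliferative libraries split 2 and 2, 1 pair against Pruned and the other against Arrested. Among the 121 to 836 genes called in both, 72.9% on average changed in opposite directions, from 57.0% to 82.7% over the 6 splits, where no relation gives 50%. This repeats, on the same libraries, the observation that prompted it, the 50% has no spread that allows for genes moving together, and chance was not excluded for the calls between Pruned and Proliferative, so the hypothesis stays open. The mean correlation with Arrested libraries was 0.728 ± 0.018 for Pruned and 0.766 ± 0.027 for Proliferative libraries (SD, n = 4; exact permutation p = 0.0857), which did not pass the test. Pruning and plant age differ together between these groups and cannot be separated by this design.

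Other splits of the same libraries were used to ask whether chance could give as many genes. For Arrested against Pruned, 1 of the 35 splits of the 8 libraries, the real one, gave as many as its 15693 genes, and the highest other gave 0. Only this rank bears on chance, and 1 of 35 is the smallest share the test can give. A mixed split puts the difference between the groups into the spread of both sides, so the 0 gives no scale for chance. The same held, with 1 of 35 and a highest other of 0, for Arrested against Proliferative (14941 genes), Reactivated against Arrested (17268), Reactivated against Pruned (8846) and Reactivated against Proliferative (8980). For the genes that set Arrested apart, 1 of 50 draws of the 16 libraries gave as many as 12662 and the highest other gave 0. For Pruned against Proliferative, 2 of 35 splits gave as many as the real 223 genes, so chance was not excluded by this count. The other was Proliferative 1, Proliferative 4, Pruned 1 and Pruned 2 against the rest, with 3281 genes, which points to a structure of the samples other than the groups. It divides the libraries by the sign of their score on the within-group axis, but the axis was drawn from the same libraries, so this is no separate evidence.

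Genes lower in Arrested than in Pruned stood next to each other in ID order 1.15 times as often as with shuffled calls, 1962 pairs against 1700 of 12688 (one-sided permutation p = 1e-04, the smallest that the permutations drawn could give). Genes higher in Arrested did so 1.07 times as often, 1354 pairs against 1264 (permutation p = 0.0014). Neighbouring IDs were taken as those 40 apart in number, and their distance on the genome was not used here. Reads of overlapping or antisense neighbours and of near-identical copies could not be told apart, which may by itself have neighbours called together. Calls were shuffled over all tested genes whatever their expression level. The cause was not tested.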
